A study of Mus musculus with 3 samples.

How the data were processed

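Total RNA from 10000000 cells of each of 3 mouse T cell populations was amplified by a T7-based linear method from 0.5 µg and labelled with Cy3, and each population was hybridized to 1 single-colour Agilent whole mouse genome array. Thymocytes and lymph node T lymphocytes came fresh from wild-type animals, and the immortalized T cells came from culture. How many animals were pooled, which retroviral vector or gene was used, how long the cells had been cultured and how the populations were purified are not given in the sources used here. The samples were grouped by their titles, and the replicate number 1 of each follows from the order of the samples alone.

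The intensity values in the scanner files were made by the authors with Agilent Feature Extraction 9.5.1.1 per the file headers, which record background subtraction by a fitted surface, a multiplicative correction for spatial trends, and a surrogate value where a spot is not above background. No scaling between arrays was applied to these intensities per the file headers. The authors also deposited 2 comparison tables, of immortalized over naive T cells and of immortalized T cells over thymocytes, with 41267 probes each. Their log10 ratios were deposited with replicate spots already combined and limited to -2 and 2, and the scaling between arrays behind them is not given in the sources used here. The p-value per probe was deposited by the authors from an error model that is not given in the sources used here. The direction of these ratios was checked against the scanner files. In the 2 tables, 4 columns per sample were not used.

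The comparisons, the main setting, the rule for named genes, 35 gene lists and all alternatives but the spike-in scaling were fixed before the data were examined. Spots marked as outliers by the scanner software, 103, 137 and 120 on the arrays of thymocytes, naive and immortalized T cells, were left out. On each array the log2 of the processed signal was taken relative to its 75th percentile over gene spots that were not outliers, and spots of the same probe were averaged. This left 41073 probes, and 101 were left out because all of their spots were outliers on an array. Probes were matched by accession to current symbols in a RefSeq gene table of the GRCm38.p6 assembly, which named 22899 probes. A further 4495 took the name of another probe with the same name in the files, and 13679 kept the name in the files. Matching through older synonyms and the pattern that separates official symbols from clone names were settled after values had been seen. The 20221 gene names with a probe well above background on at least 1 array, by the scanner software's own mark, were kept. Of these, 14263 had an official symbol, 5958 did not, and 6641 had more than 1 probe. Chromosomes and the order of genes are those of the matched gene in this table, and start and end positions are not printed, since the probes themselves were not placed on the genome.

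A gene was represented by its brightest probe, the probe with the highest mean over the 3 arrays among those well above background on at least 1. A difference was measured where the probe was well above background on both arrays, which held for 15432 genes of immortalized against naive T cells, 15274 against thymocytes and 17492 of naive T cells against thymocytes. Where the probe was well above background on 1 array only, for 4024, 4055 and 2147 genes, the difference was a bound. It is the bright value minus the higher of the probe's own value and the lowest value well above background on the dim array, which was -6.35 for thymocytes, -6.44 for naive and -5.89 for immortalized T cells. The 1 saturated spot, on the array of naive T cells, was treated in the same way. A gene was counted as higher or lower from a 2-fold difference, with 4-fold given beside it, and no p-value was computed because each group has 1 array. The spread between spots of a probe, an SD of 0.07, 0.06 and 0.08 on the 3 arrays, covers the array surface only, and no spread between animals or cultures can be had.

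Each gene list was described by its median difference, in which bounds enter at their value, and by the share of 10000 random lists of the same size, matched on brightness in 10 bins, that had a lower median. Lists with fewer than 4 genes compared got no such share. The lists cover T cell genes, pathways, sample quality and markers of other cell types, and some genes belong to more than 1 list. The genes named in the text are, for each comparison, the 10 largest measured differences in each direction among official symbols, the 5 largest bounds in each direction, up to 4 members of each list with the largest differences, members that go against their list, and always Jak1, Cd4, Cd8a, Il2ra, Myc, Trp53, Cdkn2a and Tert. Any other gene named was chosen after its values were seen, and the text says so. Counts of genes in the same direction against both fresh populations were set beside the number that independent directions would give. Arrays simulated with spot noise alone do not hold the variation between cultures or animals and give no value for unchanged samples.

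The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median of probes well above background on all 3 arrays, only such probes, no filter on dim probes with no bounds, the mean of a gene's probes, a 4-fold threshold, the authors' deposited tables, and scaling by 8 spike-in probes. A value moved by more than 1.5 times by an alternative, on the log2 scale for differences, is given beside the main value. Where several moved it, that of the setting that moved it most in a direction is given. Among named genes this covers differences of at least 2-fold, and ratios at the 100-fold limit of the deposited tables are not repeated. Smaller differences of named genes and small list medians may have moved by as much without a note. The pipeline was tested on simulated data with a spot SD of 0.08, in which 100 genes per fold size differed. At 2.83-fold, it called 95 of 100 for immortalized against naive T cells, 96 of 99 against thymocytes and 95 of 100 for naive T cells against thymocytes. At 8-fold, it called 97 of 99, 95 of 100 and 94 of 99. No unchanged gene was called in any comparison, an outcome fixed by the small simulated spot SD. All probes of a gene were given the same difference, so disagreement between probes was not simulated. Of 200 lists drawn at random from the simulated genes, 6.0%, 3.0% and 5.0% lay outside the middle 95% of random lists. Shares of this size follow from drawing both kinds of list at random and check the code only. The computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.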

Results

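Gene expression was measured in 3 populations of mouse T cells, with 1 array for each. Thymocytes, the developing T cells of the thymus, and T lymphocytes of the lymph nodes, which the labels call naive, were isolated fresh from C57BL/6 animals 8 weeks old. The remaining population was mature T cells immortalized with a retrovirus and kept in medium with human IL-2, a T cell growth factor, at 100 U/ml. No sort or gate was named for any population, and the labels give the cell type of all 3 as mononuclear cells. Each array held 43379 gene spots for 41174 probes. The share of spots well above background was 66.6% for thymocytes, 67.6% for naive T cells and 58.5% for immortalized T cells. The signal at the 75th percentile, against which each array was scaled, was 1695, 1446 and 1319 in the same order, over a median local background of 59, 61.5 and 62. With 1 array per population there were no replicates, no test across samples was possible, and the number of arrays limits the precision. All differences are on the log2 scale unless given as folds, a gene with several probes is given by its brightest probe, and "at least" marks a bound, where the probe was not well above background on 1 of the 2 arrays.

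Immortalized T cells were compared with naive T cells because the series set out to compare the expression profile of the immortalized cells with that of unmanipulated cells, and the lymph node cells were the mature fresh reference. Naive and quiescent T cell genes were lower in the immortalized T cells in 21 of 22 cases, genes of cell division were higher, and cytotoxic and effector genes split, with 16 of 32 at least 2-fold higher and 13 lower. Gzmg, Gzmc, Gzme and Gzmd, granzyme genes encoding serine proteases of cytotoxic granules, were 4660-fold, 2570-fold, 2470-fold and 1500-fold higher. The value of Gzmg in naive T cells, -6.01, lay close to the lowest value well above background on that array, -6.44. Lck, the kinase that starts T cell receptor signalling, was at least 4370-fold lower, and Tcf7, a transcription factor of T cell development and memory, was 833-fold lower. Of 19456 genes compared, 4482 were at least 2-fold higher and 4656 at least 2-fold lower in the immortalized T cells, and at 4-fold the counts were 1859 and 2534.

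Naive and quiescent T cell genes were the lowest of the T cell lists, with 21 of 22 members at least 2-fold lower and a median of -7.66 against a middle 95% of -0.59 to 0.80 for random lists of like brightness. Il7r, the receptor chain for the survival cytokine IL-7, was at least 1910-fold lower, Nsg2 was 1860-fold lower, and the homing receptor Ccr7 was at least 1520-fold lower. The median of this list was -4.62 when only probes well above background on all 3 arrays were used. T lineage transcription factors had a median of -2.63, with 10 of 14 lower and 1 higher. Ets1 was at least 2210-fold lower by its brightest probe, and its 2 probes measured on both arrays were at -7.56 and -5.8. Tbx21, the regulator of type 1 effector cells, was 316-fold lower, and Bcl11b, which holds T cell commitment, was 19.9-fold lower. In the list of the T cell receptor complex and proximal signalling, 13 of 22 genes were lower, none was at least 2-fold higher, and the median was -1.42. Next to Lck, the co-receptor Cd5 was 454-fold lower and Cd2 at least 766-fold lower. The co-receptor Cd6 was 926-fold lower by its brightest probe, with its other probe at -5.53. Some members were chosen after their values were seen because they went against the list. Among these, the CD3 chains Cd3d and Cd3g differed by -0.28 and -0.36 and Thy1 by 0.98. The brightest probe of Cd3e differed by -0.46 and its other probe by -1.73. CD4 and CD8 lineage genes had a median of -2.52, with 5 of 6 lower. Cd4 was 8.17-fold lower and Cd8a at least 1480-fold lower. The mean of the Cd4 probes was lower by more, at -5.30. The brightest probe of Cd8b1 was 3950-fold lower but its other probe was 1.05 higher, and the mean of its probes was -5.45.

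Markers of other blood cells were lower in the immortalized T cells together with these T cell lists. B cell markers had a median of -4.04 with 13 of 17 lower, and this median was -1.63 with only probes well above background on all 3 arrays. Jchain, the joining chain of secreted antibodies, was at least 2580-fold lower and Igh-6, the mu heavy chain, 467-fold lower. The brightest probe of Igh-VJ558, of the immunoglobulin heavy chain, was 7710-fold lower, although its 7 measured probes ran from -12.91 to 0.23 and the mean of its probes was -6.99, and Igl-V1, of the lambda light chain, was 1760-fold lower. Myeloid cell markers had a median of -3.82, which was -2.14 with only probes well above background on all 3 arrays, with 19 of 24 lower and 3 higher. Lyz2, the macrophage lysozyme, was 397-fold lower, whereas Fcer1g, an adaptor chain of activating receptors, was 41.3-fold higher. Natural killer cell markers had a median of -3.32 with 7 of 11 lower and 3 higher, and this median turned to 0.99 with only probes well above background on all 3 arrays. The inhibitory receptor Klra7 was 358-fold lower, and Gzma, a granzyme shared with killer T cells, was 82.8-fold higher. Gamma delta T cell genes were lower in 4 of 6 cases, with 5 of the 6 values as bounds. Their median of -1.72 ran from -3.60 without a filter on dim probes to -1.06 under quantile normalization. Erythroid markers had a median of -1.87, with 6 of 7 lower, which ran from -3.01 to -1.22 under the same settings. The haemoglobin gene Hba-a1 was 60.2-fold lower, and Car2, a carbonic anhydrase on the same list, was 160-fold higher. MHC class II genes went the other way, with a median of 0.83, 0.46 under quantile normalization, and 4 of 8 higher and 1 lower. Ciita, their master regulator, was 5.70-fold higher, and H2-Oa at least 79.3-fold lower. Markers of thymic epithelium and stroma had a median of -0.15, with 2 of 10 higher and 2 lower. Fibroblast, endothelial and lymph node stroma markers had a median of -0.26, with 2 of 13 higher and 1 lower.

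Cell division genes were higher in the immortalized T cells as a group. All but 1 of the mitosis genes, 29 of 30, were at least 2-fold higher, with a median of 3.36 against random lists between -0.28 and 0.80. The mitotic cyclin Ccnb1 was 15.8-fold higher, the kinase Cdk1 19.0-fold higher (2.60 on the log2 scale by the mean of its probes), and the cytokinesis gene Anln 45.1-fold higher (3.25 on the log2 scale under the other background correction, normexp). DNA replication genes had a median of 2.01, with 23 of 29 higher and 1 lower. Rrm2, a subunit of the enzyme that makes deoxynucleotides, was 18.2-fold higher, and the cyclin Ccne2 16.5-fold higher. G1 cyclins and kinases had a median of 1.60, with 7 of 9 higher. Ccnd1 was 31.2-fold and Cdk6 12.3-fold higher. Cell cycle brakes had a median of -0.81 but moved apart, with 5 of 22 higher and 9 lower. The stress genes Gadd45b and Gadd45a were 48.9-fold and 20.2-fold lower, while the kinase inhibitor Cdkn1a was 44.1-fold higher and Cdkn2a, which encodes p16 and p19, at least 18.8-fold higher (1.47 on the log2 scale under normexp). The tumour suppressor Trp53 differed by -0.40 by its brightest probe and by 0.85 by its other probe. Telomere maintenance genes had a median of 0.24, within random lists, with 4 of 14 higher. Nhp2, of the telomerase ribonucleoprotein, was 4.52-fold higher, and Tert, the telomerase reverse transcriptase, differed by -0.88 (-0.39 in the authors' deposited table). Lymphoid oncogenes and frequent retroviral integration targets had a median of -0.24, with 8 of 37 higher and 16 lower. Mycn was 170-fold higher, and Myc and Jak1 differed by -0.19 and -0.71. In the authors' deposited table Myc and Jak1 were at -0.53 and -1.30. Apoptosis regulators had a median of 0.47 (0.19 by the mean of probes), with 10 of 24 higher and 8 lower. The survival genes Bcl2l1 and Bcl2l2 were 15-fold and 12.6-fold higher.

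Cytotoxic and effector genes split, with 16 of 32 higher and 13 lower and a median of 1.05, which was 0.60 under quantile normalization. Gzmf was at least 12200-fold higher, and Lta, encoding lymphotoxin, was 26.7-fold lower. T cell cytokines had 6 of 19 higher and 7 lower and a median of -0.62, which ran from -2.16 in the authors' deposited table to 2.30 with only probes well above background on all 3 arrays. Csf2, a myeloid growth factor, was 253-fold higher (5.30 on the log2 scale under normexp), and Tnfsf11 at least 28.5-fold lower. Common gamma chain cytokine receptors and JAK-STAT genes had a median of -0.79, with 6 of 27 higher and 11 lower. In the authors' deposited table that median was -1.23. Il2ra, the high-affinity IL-2 receptor chain, was 46.7-fold higher, Stat4 at least 427-fold lower and Socs3 28.3-fold lower. T cell activation and checkpoint genes had a median of -1.54, with 10 of 31 higher and 17 lower, and -0.82 with only probes well above background on all 3 arrays. Havcr2, the checkpoint receptor TIM-3, was 123-fold higher, whereas Nr4a1, an early gene of receptor signalling, was 267-fold lower, Cd44 221-fold lower and Pdcd1 at least 152-fold lower. Chemokine and homing receptors had a median of -3.78, with 3 of 25 higher and 17 lower, among them S1pr1, which guides exit from lymph nodes, at least 728-fold lower. Notch receptors and targets had a median of -0.19, with 5 of 15 higher and 3 lower. The ligand Jag1 was 74.3-fold higher, and the target Dtx1 at least 1650-fold lower. Thymocyte stage genes had a median of -2.25, with 2 of 17 higher and 11 lower, Cd24a being at least 69.0-fold lower.

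Glycolysis genes had a median of 1.33 against random lists between -0.16 and 1.01, with 13 of 20 higher and 3 lower. Hexokinase Hk2 was 27.1-fold and the glucose transporter Slc2a1 7.24-fold higher, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 8.54-fold lower. Sterol and fatty acid synthesis genes had a median of 2.05 against random lists between -0.31 and 0.97, with 15 of 21 higher and 1 lower. Cyp51, an enzyme of cholesterol synthesis, was 8.01-fold higher. Ribosome biogenesis genes had a median of 1.02, with 11 of 20 higher and 1 lower, within random lists between -0.12 and 1.05. Oxidative phosphorylation genes had a median of 1.07, with 16 of 24 higher and 1 lower, just above random lists between 0.04 and 1.03. These medians were 0.61 under quantile normalization and 0.67 in the authors' deposited table. Nop2, a nucleolar methyltransferase, was 3.10-fold higher and cytochrome c, Cycs, 4.93-fold higher. Housekeeping genes had a median of 0.56, 0.28 under quantile normalization, with 4 of 14 higher. Interferon response genes were lower, with a median of -2.15, 19 of 27 lower and 2 higher. Usp18, a brake on interferon signalling, was 116-fold lower, and Ifit3 at least 175-fold lower. MHC class I presentation genes had a median of -0.20, with 1 of 10 higher. Immediate early and heat shock genes had a median of -1.5, with 11 of 18 lower and 2 higher, and Fos was 90.9-fold lower. The medians of the lists of T cell cytokines, Notch, apoptosis, telomere, oncogene, housekeeping, MHC class II, thymic stroma and fibroblast, endothelial and lymph node stroma genes also lay within random lists of like brightness. All 4 Y-linked genes compared were lower, each as a bound, with a median bound of -6.98, and Xist, which coats the inactive X, was not well above background by any of its 4 probes in either population.

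Outside the lists, the largest measured differences by the fixed rule were Gpx8, a peroxidase of the endoplasmic reticulum, 1920-fold higher, Stfa2l1, Csta2 and Cstdc6, cysteine protease inhibitors of the stefin family, 1560-fold, 857-fold and 822-fold higher, Ctsg, the serine protease cathepsin G, 1140-fold higher, and Apoc2, an apolipoprotein, 918-fold higher. The largest bounds were Rhox5, a homeobox gene of the reproductive tract, at least 21100-fold higher, Csn1s1 and Csn2, which encode milk caseins, at least 16900-fold and 5360-fold higher, and Tac4, a tachykinin gene, at least 6860-fold higher. In the other direction, Adgre5, Tpm4, Ms4a4b and Gramd3 were 1230-fold, 1160-fold, 1070-fold and 841-fold lower, and Ms4a6b, Gimap6 and Skap1 at least 4530-fold, 2510-fold and 2340-fold lower. Calls rested on size alone. Spots of the same probe differed by an SD of 0.10 in this comparison, and probes of the same gene by a robust SD of 0.40 over 4834 genes. The robust SD was taken from the median absolute deviation between 2 probes of each gene, so large disagreements hardly enter it. Of these genes, 131 had probes at least 2-fold apart in opposite directions. With only probes well above background on all 3 arrays the count of lower genes was 2926, and the median gene, 0.15 higher in the immortalized T cells, lay between -0.10 under normexp and 0.33 under spike-in scaling.

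**Figure D1:**
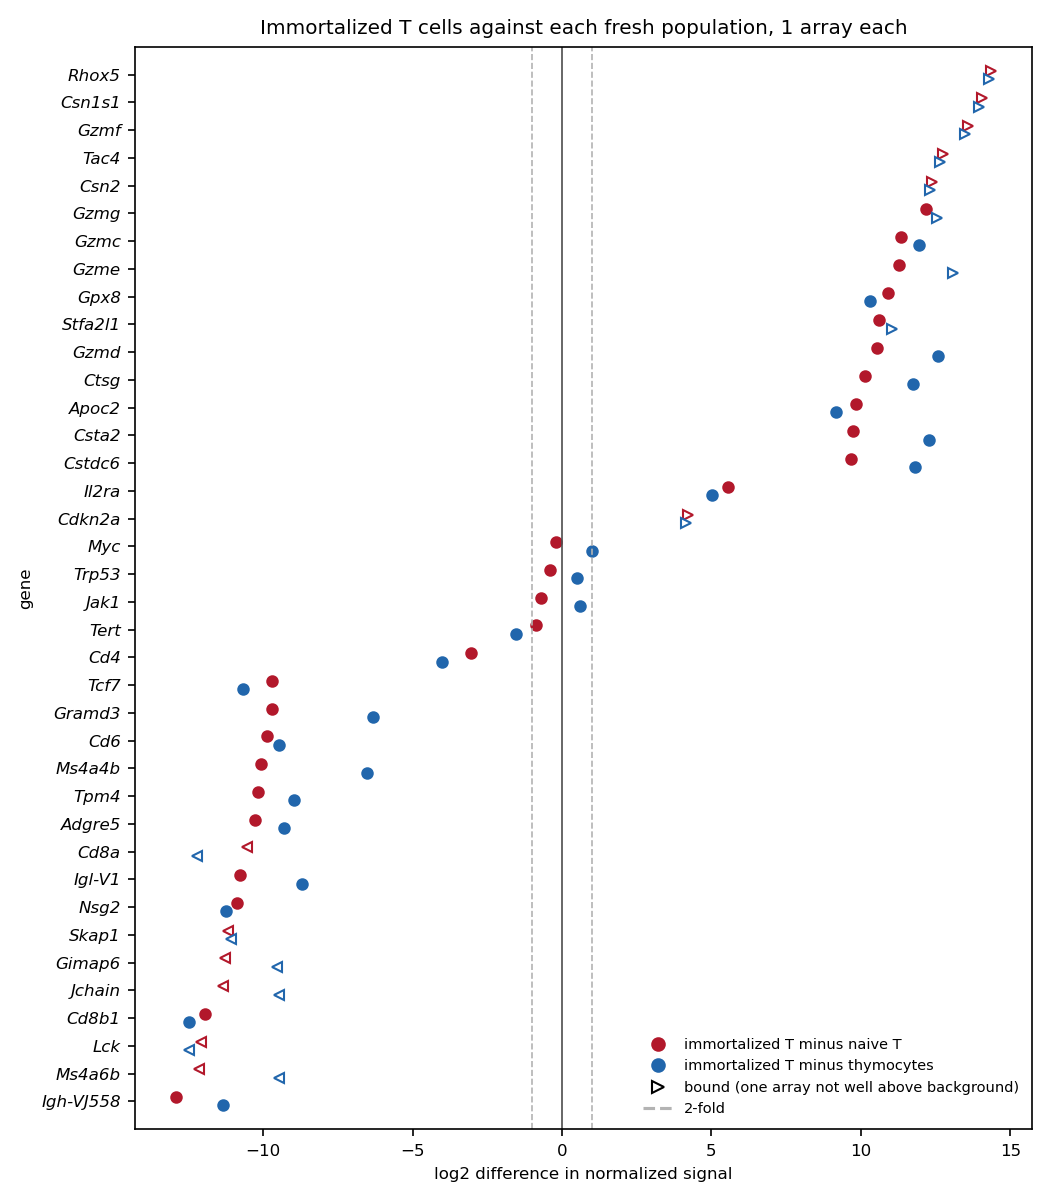
Log2 differences in normalized signal (x axis) for the genes named by the fixed rule for immortalized against naive T cells (y axis), with red for immortalized minus naive T cells and blue for immortalized T cells minus thymocytes, 1 array each. Filled circles are measured differences, open triangles are bounds, dashed lines mark 2-fold, and the values run from -12.91 for Igh-VJ558 to at least 14.36 for Rhox5, both against naive T cells.

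Against thymocytes, the immature fresh reference, the immortalized T cells had lower thymocyte stage genes in 19 of 19 cases and lower naive and quiescent T cell genes in 20 of 22, and cytotoxic and effector genes were higher in 22 of 32 cases, while most cell division genes were within 2-fold. Rag1, which cuts the T cell receptor loci for rearrangement, was at least 6180-fold lower, and Dntt, the enzyme that adds nucleotides at the joins, 1780-fold lower. Gzmd and Gzmc were 6140-fold and 3890-fold higher, and Gzmf and Gzme at least 11500-fold and 8600-fold higher. Of 19329 genes compared, 4423 were at least 2-fold higher and 5009 at least 2-fold lower, and at 4-fold the counts were 1828 and 2619.

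Thymocyte stage genes were all lower, 19 of 19, with a median of -7.23 against random lists between -0.81 and 0.82. Ccr9, a receptor for thymic chemokine, was 884-fold lower, and Ptcra, the surrogate alpha chain, at least 150-fold lower. Naive and quiescent T cell genes had a median of -4.74 with 20 of 22 lower, among them Nsg2, Tcf7 and Satb1, 2430-fold, 1630-fold and 1540-fold lower. T lineage transcription factors had a median of -2.27, with 10 of 14 lower and 2 higher. Ets1 was at least 2660-fold lower by its brightest probe and Bcl11b 38.4-fold lower, whereas Eomes, a regulator of cytotoxic cells, was 460-fold higher. The list of the T cell receptor complex had a median of -0.92 with 10 of 22 lower. Lck was at least 5750-fold and Trat1 at least 644-fold lower, and Lat, the membrane adaptor of the pathway, 504-fold lower, with Cd3d and Cd3g at -0.47 and -0.30 and the probes of Cd3e at -0.15 and -2.57. CD4 and CD8 lineage genes had a median of -4.03, with 3 of 5 lower and 1 higher, and -1.54 with only probes well above background on all 3 arrays. Cd8a was at least 4690-fold lower, Cd4 16.3-fold lower, and the brightest probe of Cd8b1 5680-fold lower, with its other probe 0.82 higher. The means of the probes were -6.49 for Cd4 and -5.83 for Cd8b1. Gamma delta T cell genes had a median of -4.45, -2.69 under normexp, with 5 of 5 lower, 4 of them as bounds. Notch receptors and targets had a median of -0.22, with 5 of 15 higher and 5 lower. Markers of other cells that were lower beside these lists were B cell markers, with a median of -2.56 and 13 of 17 lower, and myeloid cell markers, with a median of -2.43, 17 of 24 lower and 3 higher. These medians ran from -4.15 without a filter on dim probes to -1.31 under normexp for B cell markers, and from -4.08 to -0.87, with only probes well above background on all 3 arrays, for myeloid markers. Igh-6 was 402-fold and Lyz2 267-fold lower, and Fcer1g was 147-fold higher.

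Mitosis genes had a median of -0.35, with 2 of 30 higher and 6 lower, and DNA replication genes one of -0.33, with 4 of 29 lower. Both lay below the middle 95% of random lists, which began at -0.05 and -0.01, and under quantile normalization they were -0.80 and -0.88. Foxm1, the transcription factor of mitotic genes, was 2.65-fold lower, and E2f2, an activator of replication genes, 73.4-fold lower. G1 cyclins and kinases had a median of 0.68, 0.37 under normexp, with 3 of 9 higher and 1 lower. Ccnd1 and Ccnd2 were 89.2-fold and 6.62-fold higher, and Ccnd3 3.77-fold lower. Cell cycle brakes had a median of -1.60, with 4 of 22 higher and 15 lower. Cdkn1a and Cdkn2b were 206-fold and 77.4-fold higher, Cdkn2a at least 17.7-fold higher (2.71 on the log2 scale under normexp), Gadd45a 22.6-fold lower, and Trp53 differed by 0.49. Telomere maintenance genes had a median of -0.16, with 4 of 14 higher and 2 lower, and Tert was 2.92-fold lower (-1.01 on the log2 scale under quantile normalization). Lymphoid oncogenes had a median of -0.18, with 10 of 34 higher and 10 lower. Myc was 2.0-fold higher, a value of 0.64 on the log2 scale under quantile normalization, and Jak1 differed by 0.59. Apoptosis regulators had a median of 0.42, with 10 of 24 higher and 4 lower, and the death receptor Fas was 15.5-fold lower while its ligand Fasl was 133-fold higher.

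Cytotoxic and effector genes had a median of 4.48 against random lists between -0.52 and 0.62, with 22 of 32 higher and 9 lower, and Ifng, encoding interferon gamma, was 258-fold higher. Natural killer cell markers moved apart beside them, with 4 of 11 higher, 4 lower and a median of -0.72, which ran up to 4.54 with only probes well above background on all 3 arrays. The activating receptor Ncr1 was 35.5-fold higher and Klra7 42.2-fold lower. T cell cytokines had a median of -0.02, with 7 of 16 higher and 7 lower, and Il10 was 288-fold higher. Common gamma chain cytokine receptors and JAK-STAT genes had a median of -0.08, with 8 of 27 higher and 6 lower. Il2ra was 32.1-fold and Cish, a feedback inhibitor of cytokine signalling, 60.8-fold higher, and Stat4 at least 102-fold lower. Activation and checkpoint genes had a median of 0.61, 1.04 in the authors' deposited table, with 14 of 30 higher and 10 lower, and Havcr2 was 377-fold higher. MHC class I presentation genes had a median of 1.75 with 6 of 10 higher, and 0.50 by the mean of probes. Erap1, a peptidase that trims peptides for MHC class I, was 7.17-fold higher. MHC class II genes had a median of 1.90, with 7 of 8 higher and 1 lower, and H2-Aa was 5.45-fold higher. Interferon response genes had a median of -0.91, -0.46 with only probes well above background on all 3 arrays, with 3 of 27 higher and 13 lower. Chemokine and homing receptors had a median of -2.79, with 6 of 23 higher and 14 lower, which was -1.62 under normexp and -0.23 with only probes well above background on all 3 arrays.

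Glycolysis genes had a median of 1.62, with 13 of 20 higher and 3 lower, and Hk2 and Slc2a1 were 41.2-fold and 18.9-fold higher. Sterol and fatty acid synthesis genes had a median of 1.05, with 12 of 21 higher and 1 lower, and ribosome biogenesis genes a median of 1.19 with 12 of 20 higher, Gnl3 being 5.09-fold higher. Oxidative phosphorylation genes had a median of 0.92, within random lists between 0.17 and 1.05, with 11 of 24 higher and 1 lower, and 0.37 in the authors' deposited table. Housekeeping genes had a median of 0.84, with 3 of 14 higher, and 0.24 under quantile normalization. Immediate early and heat shock genes had a median of 0.18, with 5 of 18 higher and 4 lower. Ier3, a stress-response gene, was 43.6-fold higher and Fos 18.7-fold lower. Erythroid markers had a median of -0.45 over 5 genes, 0.09 under quantile normalization, with 1 higher and 2 lower. Thymic epithelium and stroma markers had a median of -0.53, with 4 of 11 lower, and fibroblast, endothelial and lymph node stroma markers one of -0.33, with 2 of 13 higher and 2 lower. Under quantile normalization these were 0.00 and 0.23. The medians of the lists of G1 cyclins, T cell cytokines, common gamma chain and JAK-STAT, activation, Notch, apoptosis, telomere, oncogene, immediate early, housekeeping, natural killer, erythroid, thymic stroma and fibroblast, endothelial and lymph node stroma genes also lay within random lists. The only sex-linked gene compared, Xist, was at least 2830-fold lower.

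Other genes named by the rule were Csta2, Cstdc6 and Ctsg, 4950-fold, 3570-fold and 3420-fold higher, Dixdc1 1740-fold higher, Spp1, which encodes the secreted protein osteopontin, 1360-fold higher, Gpx8 1280-fold higher, Speer6-ps1 1250-fold higher and the matrix gene Emilin2 1230-fold higher. Rhox5, Csn1s1 and Tac4 were at least 19900-fold, 15900-fold and 6470-fold higher. Ly6d and Ldhb, a lactate dehydrogenase subunit, were 1850-fold and 1080-fold lower. Probes of Igh-VJ558, of Glcci1 and of Arl5c differed among themselves, so that their brightest probes, 2590-fold, 884-fold and at least 2330-fold lower, do not stand for every probe of the gene. The mean of the probes was -5.11 for Igh-VJ558 and -7.40 for Arl5c. The SD was 0.10 between spots of a probe and the robust SD 0.44 between probes of a gene over 4799 genes, and 130 genes had probes at least 2-fold apart in opposite directions. With only probes well above background on all 3 arrays 3159 genes were lower, and the median gene, 0.17 higher in the immortalized T cells, lay between 0.10 by the mean of probes and 0.30 without a filter on dim probes.

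To ask which differences the immortalized T cells showed against both fresh populations, the 18564 genes compared with each were counted by direction. Against both, 3197 genes were at least 2-fold higher and 3329 at least 2-fold lower, and at 4-fold 1245 and 1641. Granzyme genes Gzmc, Gzmd, Gzme and Gzmf, the casein gene Csn1s1, the homeobox gene Rhox5, Il2ra, Cdkn1a and Ccnd1 were higher against both, and Lck, Tcf7, Ets1, Bcl11b, Cd8a and Il7r lower against both. Directions independent of each other would give 1068 and 1133 genes. Both comparisons contain the same immortalized array, so part of the excess may come from that array alone. The differences correlated across genes with r = 0.841 and a covariance of 4.10, and genes are not independent replicates. Simulated spot noise through the shared array gave r = 0.576, a covariance of 0.01 and 0 genes, a count fixed by the small spot SD, and variation between cultures or animals, which 1 array per population does not measure, is not in it. With only probes well above background on all 3 arrays, 2089 genes were lower against both.

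Naive T cells were compared with thymocytes as the difference between the fresh references themselves. Naive T cells had lower thymocyte stage and cell division genes, and higher effector, homing and interferon response genes. Arpp21, a gene of early lymphocytes, was 871-fold lower in naive T cells and Rag1 at least 8040-fold lower. The receptors S1pr1 and Ccr7 were 53.7-fold and 28.7-fold higher. Of 19639 genes compared, 3132 were at least 2-fold higher and 2875 at least 2-fold lower, and at 4-fold the counts were 1123 and 1055.

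Thymocyte stage genes had a median of -4.49, with 17 of 19 lower and none at least 2-fold higher, and -2.82 with only probes well above background on all 3 arrays. Dntt, the receptor Notch3 and Aqp11 were 95.4-fold, 114-fold and 83.4-fold lower. Mitosis genes were lower in 30 of 30 cases, with a median of -3.77, and DNA replication genes in 27 of 29, with a median of -2.46. Cenpf and Cdc45 were 21.9-fold and 14.6-fold lower. G1 cyclins and kinases had a median of -1.58, with 2 of 9 higher and 6 lower. Cell cycle brakes had a median of -0.01, with 5 of 21 higher and 6 lower, Gadd45b being 9.89-fold higher and Cdkn2c 7.28-fold lower. The probe of Cdkn2a was not well above background in either. Telomere maintenance genes had a median of -0.21, with none of the 14 at least 2-fold apart. Naive and quiescent T cell genes had a median of 1.21, with 12 of 22 higher and 2 lower, and 0.51 with only probes well above background on all 3 arrays. Dapl1 was 238-fold higher and Ccr9 22.5-fold lower. The T cell receptor complex list had a median of 0.27, with 3 of 22 higher and 2 lower, and T lineage transcription factors one of -0.19, with 5 of 14 higher and 1 lower. Eomes and Tbx21 were 72.0-fold and 11.8-fold higher. CD4 and CD8 lineage genes had a median of 0.96, with 3 of 6 higher and 1 lower, and 0.49 under normexp. Cd8a was 3.17-fold and Cd4 2.0-fold lower. Gamma delta T cell genes had a median of -0.55, with 2 of 6 lower, and 0.14 under normexp. Notch receptors and targets had a median of 0.37, 0.65 under normexp, with 5 of 15 higher and 2 lower.

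Cytotoxic and effector genes had a median of 3.40, with 28 of 31 higher and 1 lower, and the interferon gamma gene Ifng and the chemokine gene Ccl5 were 38.0-fold and 35.3-fold higher. T cell cytokines had a median of 1.57, with 12 of 20 higher and 1 lower, and 2.5 without a filter on dim probes. Common gamma chain cytokine receptors and JAK-STAT genes had a median of 1.32, with 16 of 27 higher and 2 lower, and Jak1 was 2.47-fold higher. Activation and checkpoint genes had a median of 1.91 with 24 of 31 higher, the stress-response factor Bhlhe40 being 32.7-fold higher. Chemokine and homing receptors had a median of 1.22, with 16 of 25 higher and 2 lower. Interferon response genes had a median of 1.25 with 16 of 27 higher, and MHC class I presentation genes one of 1.23 with 6 of 10 higher. Mx1, an antiviral GTPase, was 5.17-fold higher and H2-K1 4.80-fold higher. Immediate early and heat shock genes had a median of 1.74 with 11 of 18 higher, and Atf3 was 37.5-fold higher. Lymphoid oncogenes had a median of 0.56, 0.37 with only probes well above background on all 3 arrays, with 17 of 36 higher and 5 lower, and Myc was 2.27-fold higher. Markers of other cells were higher beside these lists. Natural killer cell markers had a median of 1.86, with 10 of 11 higher and 1 lower, myeloid cell markers one of 1.03, with 12 of 24 higher and 3 lower, erythroid markers one of 1.77, with 7 of 7 higher, and MHC class II genes one of 1.01, with 4 of 8 higher. The median of the myeloid markers was 1.64 with only probes well above background on all 3 arrays. Klra7 was 8.48-fold, the lysosomal protease gene Ctss 6.34-fold and Car2 3.97-fold higher. B cell markers had a median of 0.22, within random lists, with 5 of 17 higher, Cd72 being 8.72-fold higher.

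Glycolysis genes had a median of 0.39, with 3 of 20 higher and 3 lower, and sterol and fatty acid synthesis genes one of -0.50, with 6 of 21 lower. Scd2, a fatty acid desaturase, was 6.50-fold lower. Ribosome biogenesis genes had a median of 0.45, with 2 of 20 higher and 1 lower, and 0.29 under quantile normalization. Oxidative phosphorylation genes had a median of -0.29 and housekeeping genes one of 0.11, with none of 24 and 2 of 14 genes at least 2-fold apart. Apoptosis regulators had a median of 0.34, 0.60 with only probes well above background on all 3 arrays, with 7 of 24 higher and 2 lower. Thymic epithelium and stroma markers had a median of -0.90, with 5 of 11 lower, which was -0.09 with only probes well above background on all 3 arrays. Fibroblast, endothelial and lymph node stroma markers had a median of 0.11, with 4 of 15 lower. The medians of the lists of the T cell receptor complex and of T lineage transcription factor, Notch, cell cycle brake, apoptosis, telomere, glycolysis, housekeeping, gamma delta and fibroblast, endothelial and lymph node stroma genes lay within random lists. Sex-linked genes split, with 4 of 5 higher. Xist was at least 4140-fold lower in naive T cells, and the Y-linked genes Eif2s3y and Ddx3y at least 513-fold and 326-fold higher.

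Several genes known from platelets were among the largest measured differences. Pf4, Myl9, Alox12 and Cavin2 were 113-fold, 108-fold, 101-fold and 100-fold higher in naive T cells, Vwf 71.1-fold higher (3.80 on the log2 scale by the mean of its probes), and Ppbp at least 580-fold higher. Trim12a was 764-fold higher, and the brightest probe of Mgst3 335-fold higher, with its other probe at -2.28 and a mean of 3.05. Chrna9, Arsi, Endou and Morc1 were 302-fold, 292-fold, 258-fold and 117-fold lower, and the probes of Syt13 were at -8.80 and -2.59, with a mean of -5.69. The SD was 0.09 between spots of a probe and the robust SD 0.25 between probes of a gene over 5401 genes. Of the genes called, 52.1% were higher in naive T cells, which was 71.6% under normexp, where 1552 genes were lower and the median gene was 0.27 higher in place of 0.02 (-0.09 without a filter on dim probes), while with only probes well above background on all 3 arrays 2046 genes were higher and 1860 lower.

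**Figure D2:**
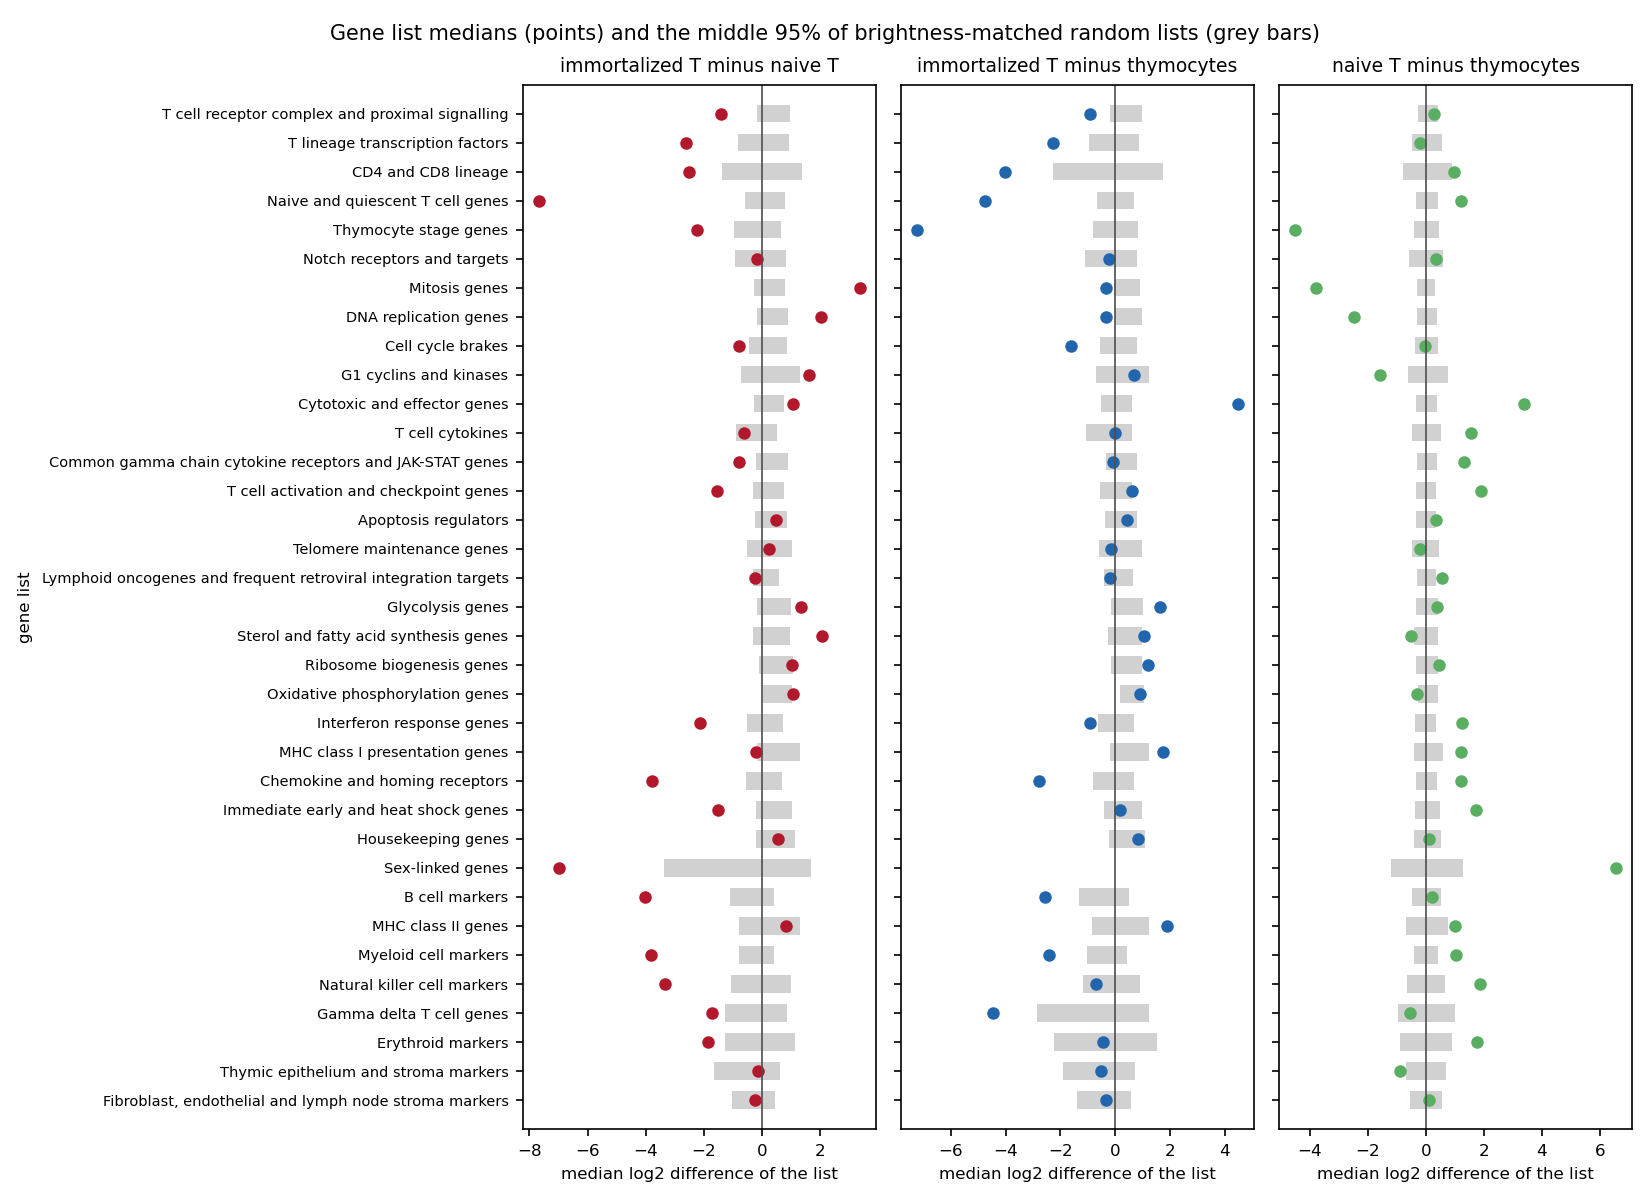
Median log2 difference (x axis) of each gene list (y axis) in the 3 comparisons, points for the lists and grey bars for the middle 95% of random lists matched on brightness. Naive and quiescent T cell genes lie at -7.66 and -4.74 in the immortalized T cells against naive T cells and thymocytes, and mitosis genes at 3.36 against naive T cells, -0.35 against thymocytes and -3.77 for naive T cells against thymocytes.

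The authors' deposited table for each of the 2 comparisons with immortalized T cells gives a ratio and a p-value per probe from an error model that is not named. In the authors' deposited table against naive T cells, 7371 probes were at least 2-fold higher and 6997 at least 2-fold lower at their p under 0.01. The authors' deposited table against thymocytes gave 7318 and 7586 probes by the same measure. Ratios of the authors' deposited table are limited to 100-fold, which 803 and 827 probes reached, Lck, Tcf7, Gzmc and Rhox5 among them in both. Ratios of the authors' deposited table correlated across probes well above background on both arrays with those from the scanner files at r = 0.974 and 0.970, with a median offset of 0.13 and 0.15. Il2ra was 5.56 and 4.98 higher on the log2 scale in the authors' deposited table, beside 5.55 and 5.01 from the scanner files.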

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

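The tests of a dimmer immortalized array and of a smaller share of T cells, and the spike-in scaling among the scalings, were chosen after the results were seen, and the shares at the levels of the Y-linked genes were added after that at the level of Xist was seen.

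The immortalized T cells lay on opposite sides of the fresh populations for a small set of genes. At least 2-fold each, 110 genes were higher than in naive T cells and lower than in thymocytes, and 80 were lower than in naive T cells and higher than in thymocytes. At 4-fold these were 15 and 6. The difference between the comparisons was not tested. Among genes chosen after their values were seen, Notch3, a receptor of thymocyte development, was 2.63 higher than in naive T cells and lower than in thymocytes by -4.21, and the replication regulator E2f8 was at 2.29 and -2.27. In the other direction the stress gene Atf3 was at -2.68 and 2.55, and the chemokine receptor Cxcr3 at -1.95 and 1.87.

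Naive and quiescent T cell genes were lower in the immortalized T cells, with a median of -7.66 against naive T cells. A dimmer immortalized array would leave this median within random lists of like brightness. Their middle 95% ended at -0.59 against naive T cells and -0.67 against thymocytes. Brightness was the mean of the 2 arrays compared, so the immortalized array itself entered the match. Lists matched on the fresh array alone were not drawn. The scaling between arrays is also argued against, since the median stayed between -7.70 and -7.31 under 3 other scalings. A smaller share of T cells in the culture, as the whole cause, would lower all genes that only T cells express by about the same amount. The median of the T cell receptor complex list, at -1.42, lay 6.25 (SE 1.49, by bootstrap over genes only) above that of the naive and quiescent list. This gap cannot decide, because the list may hold genes that other cells express too, and its members split. Lck was at -12.09 as a bound, Cd2 at -9.58 as a bound and Cd5 at -8.83. Cd6 was at -9.86 by its brightest probe and -5.53 by its other. The brightest probe of Cd3e was at -0.46, its other probe at -1.73, and Cd3d and Cd3g stayed within 2-fold. A lower expression of the naive and quiescent genes in the immortalized T cells themselves may remain, as a hypothesis. A smaller share of T cells, culture with IL-2, immortalization, clonal outgrowth and the loss of other cells of the lymph node were not tested against each other.

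Sex-linked transcripts split the 3 samples, with Xist well above background in thymocytes only and Ddx3y, Eif2s3y, Kdm5d and Uty in naive T cells only. Failed hybridization on the immortalized array of probes as bright as Xist is argued against, as 1.88% of the 586 other genes within 1 log2 of its level in thymocytes were below background there. The same holds at the levels of Eif2s3y, Ddx3y and Kdm5d in naive T cells, where the shares were 2.45%, 3.42% and 6.29%. For the dimmer Uty it stays open, since the share, 22.3%, was not under the 20% set as the limit, although most such genes were above background. A failure of the sex-linked probes alone was not tested. A second active X in female immortalized T cells is argued against too, since X-linked genes lay 0.08 (SE 0.06) above autosomal genes against naive T cells. That SE is a bootstrap over genes, which are not independent replicates, and it holds no variation between cultures or animals. Fresh samples pooled from animals of different sex may be the source of the split between thymocytes and naive T cells, as 4 of 4 X-linked genes that escape inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, were lower in naive T cells, with a median of -0.70. Whether the immortalized T cells were male and lost the Y or female and lost Xist was not tested, and the labels give no sex.

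Genes known from platelets were higher in naive T cells than in thymocytes. On 16 further platelet genes, listed before their values were seen, the median was 3.64, above all random lists, and 14 were at least 2-fold higher and none at least 2-fold lower. Brighter dim probes on the array of naive T cells are argued against, since random lists of like brightness ended at 0.56. Platelets carried over with the lymph node cells are a candidate source, with levels of 2.83 for Ppbp, 2.28 for Myl9 and 1.83 for Pf4 against the 75th percentile of the array, and no sort or gate that would remove them is named. On the immortalized array Gng11, Itgb3, P2ry12 and F2rl2 were brighter than in naive T cells, so not every gene of the list belongs to platelets alone in these samples.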

How the results depend on the processing

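Scaling by spike-in probes was chosen after seeing the data, and the other settings were planned. Of the 56 gene list medians of at least 2-fold, the number that kept their direction was 56 of 56 under normexp, quantile normalization, the median of detected probes, no filter, the mean of probes and spike-in scaling, and 38 of 38 in the authors' deposited tables, which hold no comparison of naive T cells with thymocytes. They stayed at least 2-fold in 55, 50, 55, 56, 54 and 54 cases and in 35 of 38. With only probes well above background on all 3 arrays, 51 of 52 kept their direction and 47 stayed at least 2-fold. The natural killer cell markers of immortalized against naive T cells turned to 0.99, since it then holds 7 of its 11 members and 4 lower ones drop out. That filter also gave 2926 genes lower than in naive T cells, 3159 lower than in thymocytes, 2089 lower than in both, and 3906 genes for naive T cells against thymocytes, 2046 higher and 1860 lower, because genes seen as bounds drop out. Under normexp 1552 genes were lower in naive T cells than in thymocytes, and the cause was not tested. The 4-fold threshold gave by its construction fewer genes, 4393 against naive T cells (1859 higher, 2534 lower), 4447 against thymocytes (1828 and 2619), 2178 for naive T cells against thymocytes (1123 and 1055) and 2886 against both (1245 and 1641). All other counts of genes stayed within 1.5 times. Of 442 values of named genes at least 2-fold apart, 438 kept their direction under the mean of probes and 437 under normexp. By the mean of probes H2-D1 turned to -0.31 against thymocytes and -0.14 for naive T cells against thymocytes, and Pecam1 to -0.20 against naive T cells and -0.65 against thymocytes. Under normexp Tcrg-V2 turned to 0.09 for naive T cells against thymocytes, Lum came to 0.00 against naive T cells, and Lum, Dcn and Ccl21c came to 0.00 for naive T cells against thymocytes. The cause was not tested for these genes. No paired analysis was possible because each group has 1 array, and the replicate number 1 follows from the order of the samples alone. Signal over background limits the bounds: 58.5% of spots on the immortalized array were well above background, against 66.6% and 67.6% on the others. Folds are lower limits only where the probe was not well above background on 1 of the 2 arrays. Some measured folds also rest on dim values close to the lowest value well above background. Examples in naive T cells are Gzmg at -6.01 and Stfa2l1 at -5.93, beside -6.44.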

Other observations

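The genes below were chosen after their values were seen, and no explanation of them was tested. In 3 clusters of related genes, several neighbours in the RefSeq gene table were higher in the immortalized T cells, and whether neighbouring genes were so more often than others was not tested. On chromosome 14, Ctsg, Gzmb, Gzmc, Gzmd, Gzme, Gzmf, Gzmg, Gzmn, Mcpt8 and Cma1, serine protease genes of killer cells and mast cells, were all at least 2-fold higher than in both fresh populations, while Mcpt4 in the same cluster was higher by at least 1.70 and 0.61. Gzmn was at least 1110-fold higher than in naive T cells, Gzmb 96.5-fold, Mcpt8, a basophil and mast cell protease, at least 34.6-fold, and Cma1, mast cell chymase, 11-fold. Khnyn, which lies outside this cluster and encodes no such protease, was 5.70-fold higher than in naive T cells. Against thymocytes Gzmn was at least 1050-fold higher, Gzmb 467-fold and Khnyn 8.57-fold. In the stefin cluster of chromosome 16, Stfa2 was 292-fold and Stfa3 19.5-fold higher than in naive T cells. Csn3, another casein gene beside Csn1s1 and Csn2 on chromosome 5, was at least 85.2-fold higher than in naive T cells and at least 80.4-fold higher than in thymocytes.

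Probes for the T cell receptor loci differed from each other in the immortalized T cells. The 3 probes of Tcrb-V13 designed on 1 shared transcript sequence differed by 0.13, 0.21 and 0.56 between immortalized and naive T cells. A further probe of this name was 4.78 higher, and the other 2 were well above background in both fresh populations and not in the immortalized T cells. Of the 3 probes of Tcra, the receptor alpha chain locus, 1 was measured in the immortalized T cells and was at -9.44 against naive T cells and -8.64 against thymocytes, and the others were not well above background there. The 3 probes named Tcrg, of the gamma chain locus and outside the gene lists, were measured on all arrays. They differed by 0.77, -0.49 and 0.47 against naive T cells and by -0.89, -2.02 and -0.70 against thymocytes. The probes of Tcrg-C and Tcrg-V2 were not well above background in the immortalized T cells. Different rearranged receptors were not resolved, since the probes were not placed on the variable and constant segments.

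By chromosome, the median difference between immortalized and naive T cells was highest for chromosome 13, at 0.43 over 567 genes, above all of 2000 random lists matched on brightness, and 0.29 for chromosome 1. It was lowest for chromosome 12, at 0.01, and chromosome 17, also at 0.01. Against thymocytes, chromosomes 13 and 14 both had a median of 0.35. Medians as far out among random lists also occurred between the fresh populations. For naive T cells against thymocytes, chromosome 15, at 0.14, lay above all random lists and chromosome X, at -0.11, below all. Xist and Y-linked transcripts also split these populations. A difference of sex may therefore enter the median of chromosome X, which was not tested. The copy number of the chromosomes was not measured.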
